A study of Arabidopsis thaliana with 8 samples.

How the data were processed

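RNA was profiled in leaves of 4-week-old Arabidopsis plants grown at 9 per pot, 22 degrees Celsius, 75% humidity and 12 h of light. Per the labels, leaves were injected with Pseudomonas syringae pv. tomato DC3000 avrRpt2 at 100000000 cfu per ml and collected after 6 h. For each genotype, RNA came from a pool of 2 leaves per plant over 3 pots. Total RNA (1 µg) was extracted with Trizol, amplified with an amino allyl kit and labelled with Alexa555, and hybridised to the Arabidopsis Pathoarray, an oligonucleotide array for pathogen-responsive genes. The 8 arrays were grouped by their 4 genotype labels, with 2 sets each, which the series calls biological replicates. Because genotyping assigned the blind plants to ndr1-1, the main ndr1-1 comparison averages both labels.

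The deposited table holds 1 normalized value per probe and array for 576 probes, on a log2 scale. The deposited values do not state their log base. They were read as log2 because natural logs would put the brightest value at a signal of 1488265, above the 16-bit limit of 65535. If the base were another, every fold change would scale with it, while the counts and p-values would not. How the authors normalized the values, and whether they subtracted background, is not stated. In all, 7 values lay below 0 and the brightest value per array ran from 11.4 to 14.2. The values were used as deposited, with no filter and no further scaling. The array annotation named a gene for 181 probes, each probe with 1 gene, and 180 of these matched the reference gene table. The other 395 probes were tested and counted under their probe numbers. No genome build was given, so no coordinates are printed.

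All 8 arrays entered 1 fit in limma 3.58.1 under R 4.3.3, with 4 group means, 4 residual degrees of freedom and empirical Bayes moderation (4.18 prior degrees of freedom). Tests are two-sided and Benjamini-Hochberg adjusted over the 576 probes within each comparison. A probe is called at an adjusted p under 0.05. The 6 comparisons were rps2-101C, ndr1-1 over both labels, ndr1-1 alone and ndr1-1blind alone, each minus Col-0, ndr1-1blind minus ndr1-1, and ndr1-1 over both labels minus rps2-101C. Standard errors are the moderated ones. No comparison has 3 arrays in each group, so other splits of the samples were not counted. The labels name a set 1 and a set 2, and whether the genotypes of a set were grown and infected together is not stated. A fit with the set as a block was run as an alternative for every comparison. Set deviations correlated across probes with r of 0.77 between ndr1-1 and ndr1-1blind, 0.44 and 0.37 between Col-0 and these labels, -0.19 between Col-0 and rps2-101C, and -0.06 and 0.08 between rps2-101C and ndr1-1 and ndr1-1blind.

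On simulated data with 200 of 576 genes changed and 20 simulations, the fit called 49.3% of genes changed by 1 (log2) and 95.7% of genes changed by 2 in ndr1-1, with 2.94% false calls. In rps2-101C it called 34.3% and 91.5%, with 3.75% false calls. The simulated arrays were independent, while the set deviations of the 2 ndr1-1 labels correlated at 0.77, so the rates for ndr1-1 may be too favourable. Correlations of fold changes were set beside 100 simulations of unchanged mutants that share the Col-0 arrays. Those within a set were set beside 100 that share 1 Col-0 array.

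The named genes follow a rule. It takes the 10 highest and 10 lowest called genes on the same side of Col-0 in both sets for each mutant, 5 and 5 for the mutants against each other, and the 3 smallest p-values for the blind label against ndr1-1. It adds up to 4 called members of each list, or 2 members with values where none was called. The rule, the comparisons, the tests, most of the alternatives and 16 gene lists were fixed before the data were examined. As most probes have no name, the rule was applied among the named probes, and a few unnamed probes are given beside them. Of the 16 lists, 1 had at least 3 members among the named probes (WRKY transcription factors), 7 had 1 member and 8 had none. A further 12 lists were written from the probe names before any fold change was computed, which made 13 lists tested. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, each adjusted over the 13 lists. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. On simulated lists of 5 genes, with all other genes unchanged and unadjusted p under 0.05, camera and fry called 100% of lists shifted by -1.5 (log2) in ndr1-1 and 4% of unshifted lists. With the other probes at their observed changes and p adjusted over 13 lists, camera called 0% of lists shifted by -1 in either mutant, and 13.5% in rps2-101C and 0% in ndr1-1 at -1.5. Fry called 17.0%, 73.5% and 94.5% at shifts of -0.5, -1 and -1.5 in rps2-101C, and 45.0%, 93.5% and 99.5% in ndr1-1. All of these list simulations drew independent genes and arrays. In the data the estimated correlation between members was 0.92 for the WRKY list and 0.46 for the chaperones, so the simulated rates may be too favourable.

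The alternatives were the set block, median centring, quantile normalization, leaving out the dimmest 25% of probes, fitting only the groups compared, an intensity trend with robust shrinkage and an added minimum change of 1 (log2). The others were a statistic modelled on SAM with the empirical false discovery rate from the blind label, and leaving out each array. Centring on a set of reference genes, crossed set numbers, fry with each array centred and averaging the ndr1-1 labels within each set were added after seeing the data. RPS2 and NDR1 are not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.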

Results

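Gene expression was measured in leaves of Arabidopsis thaliana injected with Pseudomonas syringae pv. tomato DC3000 carrying the effector gene avrRpt2 and harvested 6 h later. The effector is recognised in Col-0, the wild type, by the resistance protein RPS2, and NDR1 is a membrane-associated protein that RPS2 needs for full signalling. Col-0 was set beside rps2-101C, a mutant of RPS2, and ndr1-1, a mutant of NDR1. Another label, ndr1-1blind, covered plants whose genotype the experimenter did not know and which genotyping later assigned to ndr1-1. Each of the 4 labels had 2 arrays, 1 from each of 2 sets of plants, so that ndr1-1 had 4 arrays in all. Each array gave 576 probe values, of which 181 belonged to probes with a gene name. The median value per array lay at 4.65 and 4.78 (log2) in Col-0, 4.29 and 4.36 in rps2-101C, 3.95 and 4.11 in ndr1-1 and 4.00 and 4.21 in ndr1-1blind, for sets 1 and 2 in that order. The number of arrays limits the precision. All 8 arrays come from infected leaves and no uninfected leaves were analysed here, so a value lower than in Col-0 is not shown to be a loss of induction. RPS2 and NDR1 were not among the named probes, so the genotype labels were not checked from expression. Whether a probe separates its gene from close relatives was not checked, which applies most to the HSP70, glutathione transferase, tubulin, histone H3 and PDF1.2 genes. On the first principal component, which held 73.6% of the variance, the Col-0 arrays lay at -19.5 and -30.7, the rps2-101C arrays at -0.52 and 0.72, and the 4 ndr1-1 arrays between 4.78 and 19.6. The component was computed on the deposited values, and the arrays lay on it in nearly the order of their medians. An array-wide shift and a difference between genotypes cannot be told apart on it.

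The comparison of rps2-101C with Col-0 asks which transcripts differ when the receptor for the effector is mutated. The largest named decreases were in AT1G05340, a small cysteine-rich transmembrane protein, Hsp70-2 (AT5G02490), a cytosolic HSP70 chaperone, and AT1G26380, a berberine bridge-type oxidase. AT1G05340 had a mean of 7.32 ± 0.74 (SD, n = 2) in Col-0 and 2.83 ± 0.32 (SD, n = 2) in rps2-101C, a log2 fold change of -4.48 (SE 0.53, adjusted p = 0.00769). Hsp70-2 was lower by a log2 fold change of -3.75 (SE 0.71, adjusted p = 0.0144) and AT1G26380 by -3.51 (SE 0.53, adjusted p = 0.00769). Fewer named genes were higher: AT3G28270 at 2.49 (SE 0.56, adjusted p = 0.0238), the beta-tubulin TUB6 (AT5G12250) at 2.03 (SE 0.33, adjusted p = 0.0086) and the vacuolar invertase AT1G62660 at 1.51 (SE 0.34, adjusted p = 0.0238). The other 7 of the 10 lowest named genes had log2 fold changes between -2.83 and -1.98. They were AT4G39670 of the glycolipid transfer protein family, the methyltransferase AT3G54150, the beta-glucosidase BGLU45 (AT1G61810), AT2G14290, the small heat shock protein AT2G29500, AT1G03220 of the aspartyl protease family and the carboxylesterase-like AT1G68620. Adjusted p-values of these 7 ran from 0.0077 in AT2G14290 to 0.0433 in AT4G39670. Among probes without a gene name, probes 415 and 210 were highest, at 3.15 and 3.12, and probes 256 and 69 lay at -4.42 and -3.54.

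In total, limma called 73 of 576 probes in rps2-101C, 16 higher and 57 lower, and 18 named genes were among them, 3 higher and 15 lower. All 73 lay on the same side of Col-0 in both sets, which was likely in advance, as the calls come from the same arrays. The share of calls that were lower, 78.1%, was 61.1% (28 higher, 44 lower) with each array centred on its median and 63.0% (20 higher, 34 lower) after quantile normalization. The median change of all probes was -0.17 on the deposited scale, and centring raised each change by 0.39. With the set as a block the count was 117, 28 higher and 89 lower. Set deviations of Col-0 and rps2-101C correlated at -0.19, so the blocked calls in rps2-101C rest on a pairing that is not stated and not seen. This comparison rests on few arrays: the count was 14 without the set 2 Col-0 array, 0 without the set 1 rps2-101C array and 4 without the set 2 rps2-101C array. The call of AT1G05340 ended only in the second of these, and those of the other named genes above ended in all 3. The call of AT1G62660 also ended without the set 1 Col-0 array, that of AT2G29500 with median centring, and those of Hsp70-2, AT4G39670, AT2G29500 and AT1G68620 with quantile normalization.

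Among the gene lists, the 5 chaperones had the lowest mean in rps2-101C, -2.14, with 2 of 5 lower (Hsp70-2 and AT2G29500) and 4 of 5 when adjusted over the list alone. With the set as a block 4 of 5 were lower, with AT3G09440 at an adjusted p of 0.0103 and AT5G48570, named after its values were seen, at 0.0374. The list did not pass camera (adjusted p = 0.055; adjusted p = 0.924 with an estimated correlation) or fry (adjusted p = 0.242), and its mean with each array centred was -1.75. Of the 4 WRKY transcription factors, 1 was lower, WRKY6 (AT1G62300), at -1.87 (SE 0.34, adjusted p = 0.0123), and also 1 when adjusted over the list alone. The WRKY mean was -0.97 (camera adjusted p = 0.686, fry adjusted p = 0.488), -0.52 without the set 2 Col-0 array, -1.43 without the set 1 Col-0 array and -0.58 with each array centred. AT1G03220, at -2.08 (SE 0.42, adjusted p = 0.018), was the 1 of 4 aspartyl protease family members that passed, with a list mean of -0.64 (-0.25 centred). The WRKY6 and AT1G03220 calls ended without the set 2 Col-0 array and without either rps2-101C array. Without the block, no member passed in the other lists, whose means were -0.56 for 4 receptor-like kinases (1 lower when adjusted over the list alone), -0.53 for 5 EF-hand calcium-binding proteins and -0.45 for 4 chitinase and PR-6 genes. The means were -0.44 for 7 UDP-glycosyltransferases, -0.34 for 7 membrane traffic genes, -0.08 for 3 vacuolar proton ATPase subunits and 0.15 for 4 respiratory chain subunits. They were 0.16 for 3 histone H3 genes, 0.31 for 5 sulfur assimilation and glucosinolate genes and 0.43 for 3 class III peroxidases. With the set as a block 3 members of these lists were lower: CHI (AT2G43570; adjusted p = 0.00649, against 0.104), the receptor-like kinase AT3G09010 (adjusted p = 0.0208, against 0.0643) and UGT76B1 (AT3G11340; adjusted p = 0.0408, against 0.066). The blocked calls in this paragraph rest on a pairing not seen between Col-0 and rps2-101C. With each array centred AT2G25450 of the sulfur and glucosinolate list was higher (adjusted p = 0.0438). Centring moved the means to -0.17 for the receptor-like kinases, -0.14 for the EF-hand proteins, -0.06 for the chitinase and PR-6 genes and -0.05 for the UDP-glycosyltransferases. It moved them to 0.53 for the respiratory chain, 0.55 for histone H3, 0.70 for the sulfur and glucosinolate genes and 0.82 for the peroxidases. With other scalings the sign flipped for membrane traffic (0.04 median-centred), the vacuolar proton ATPase (0.31 median-centred), the EF-hand proteins (0.08 quantile-normalized) and the chitinase and PR-6 genes (0.12 quantile-normalized).

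The comparison of ndr1-1 with Col-0, over 4 ndr1-1 arrays under both labels, asks the same of the signalling protein. The lowest named genes were again Hsp70-2, at -5.06 (SE 0.61, adjusted p = 0.000698), AT1G05340 at -4.61 (SE 0.46, adjusted p = 0.000452) and AT1G26380 at -4.38 (SE 0.46, adjusted p = 0.000567). Hsp70-2 had a mean of 9.70 ± 1.53 (SD, n = 2) in Col-0 and 4.64 ± 0.63 (SD, n = 4) in ndr1-1. They were followed by the chitinase CHI at -4.07 (SE 0.70, adjusted p = 0.00301), the HSP70 chaperone AT3G09440 at -3.91 (SE 0.65, adjusted p = 0.00256), and UGT76B1. UGT76B1, which attaches glucose to isoleucic acid and salicylic acid, lay at -3.85 (SE 0.63, adjusted p = 0.00242). The remaining 4 of the 10 lowest were AT3G54150 at -3.64, the glutaredoxin GRX480 (AT1G28480) at -3.59, AT3G13950 at -3.49 and AT4G39670 at -3.43, with adjusted p-values from 0.000633 (GRX480) to 0.004 (AT4G39670).

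Among the named genes higher in ndr1-1, CCL (AT3G26740) led at 2.15 (SE 0.40, adjusted p = 0.00428), before AT1G62660 at 1.83 (SE 0.29, adjusted p = 0.00229) and AT3G28270 at 1.60 (SE 0.48, adjusted p = 0.032). TUB6 lay at 1.22 (adjusted p = 0.0121) and the GDSL lipase AT3G16370 at 1.37 (adjusted p = 0.0354). The dehydrin COR47 (AT1G20440) lay at 1.13 (adjusted p = 0.0369), the photosystem II chlorophyll-binding protein LHCB4.3 (AT2G40100) at 1.12 (adjusted p = 0.0487). The PCI-domain protein AT5G15610 (adjusted p = 0.0112) and AT2G26690 of the nitrate and peptide transporter family (adjusted p = 0.0371) lay between 0.92 and 1.37. The histone H3.3 gene AT4G40030, at 0.92 (adjusted p = 0.0312), was the last of 10 named genes that were higher. Among probes without a gene name, probe 210 was highest at 3.12, and probe 69 was lowest at -6.51 (SE 0.75, adjusted p = 0.000633), before probe 256 at -5.98.

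In total, limma called 208 of 576 probes in ndr1-1, 48 higher and 160 lower, and all 208 lay on the same side of Col-0 in both sets. That too was likely in advance, as the calls come from the same arrays. Of the 181 named genes, 10 were higher and 53 lower. The share of calls that were lower, 76.9%, was 43.9% (125 higher, 98 lower) with each array centred on its median and 47.0% (115 higher, 102 lower) after quantile normalization. Centring shifts every change by a constant, and quantile normalization gives all arrays the same distribution of values. Both therefore move the balance of higher and lower calls without fixing it, and do not show which balance is right. The median change of all probes on the deposited scale was -0.36, and centring raised each change by 0.65. Of the 208 calls, 146 were kept with centring and 150 with quantile normalization, with 0 calls in the opposite direction. With the set as a block the count was 243, 60 higher and 183 lower. The 4 ndr1-1 arrays are not independent, as the labels of a set deviated together (r of 0.77 across probes), so SD and SE values over 4 arrays may be too small. With the labels of each set averaged, 163 probes were called, 30 higher and 133 lower. The count was 115 without the set 2 Col-0 array, which also ended the calls of 7 higher genes named above (AT3G28270, TUB6, AT3G16370, COR47, LHCB4.3, AT2G26690 and AT4G40030). The calls of AT3G16370 and LHCB4.3 also ended without either array labelled ndr1-1, the set 1 blind array or either rps2-101C array, and that of COR47 without the set 2 ndr1-1 array, either blind array or either rps2-101C array. Those of AT2G26690 and AT4G40030 also ended without the set 1 Col-0 array or any of the 4 ndr1-1 arrays, that of AT3G28270 without either set 1 ndr1-1 array, and that of AT5G15610 without the set 1 Col-0 array. The calls of the 10 lowest named genes, CCL and AT1G62660 held without any single array.

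**Figure D1:**
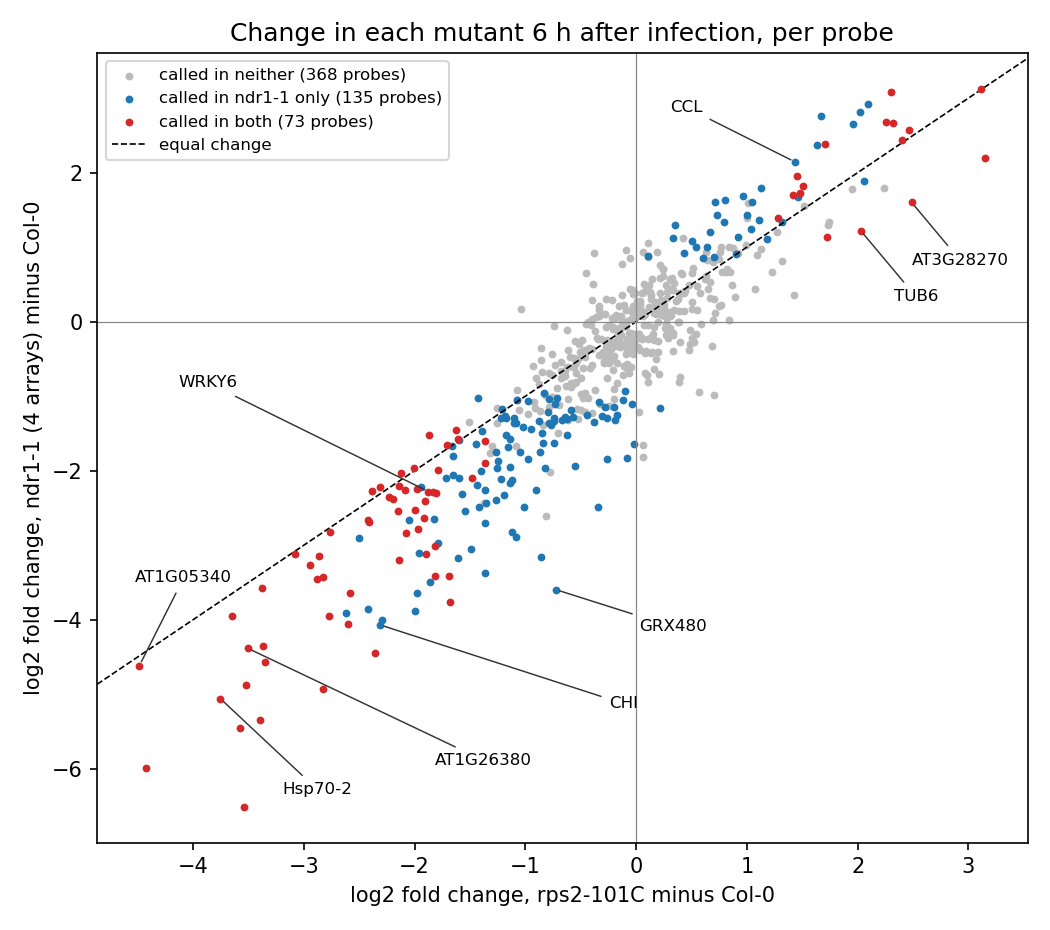
Log2 fold change of each of the 576 probes in rps2-101C (horizontal axis) and in ndr1-1 over both labels (vertical axis), each against Col-0, with the dashed line at equal change. Red marks the 73 probes called in both comparisons, blue the 135 called in ndr1-1 and not in rps2-101C, and grey the rest; Hsp70-2 lies at -3.75 and -5.06, and GRX480 at -0.73 and -3.59.

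**Figure D2:**
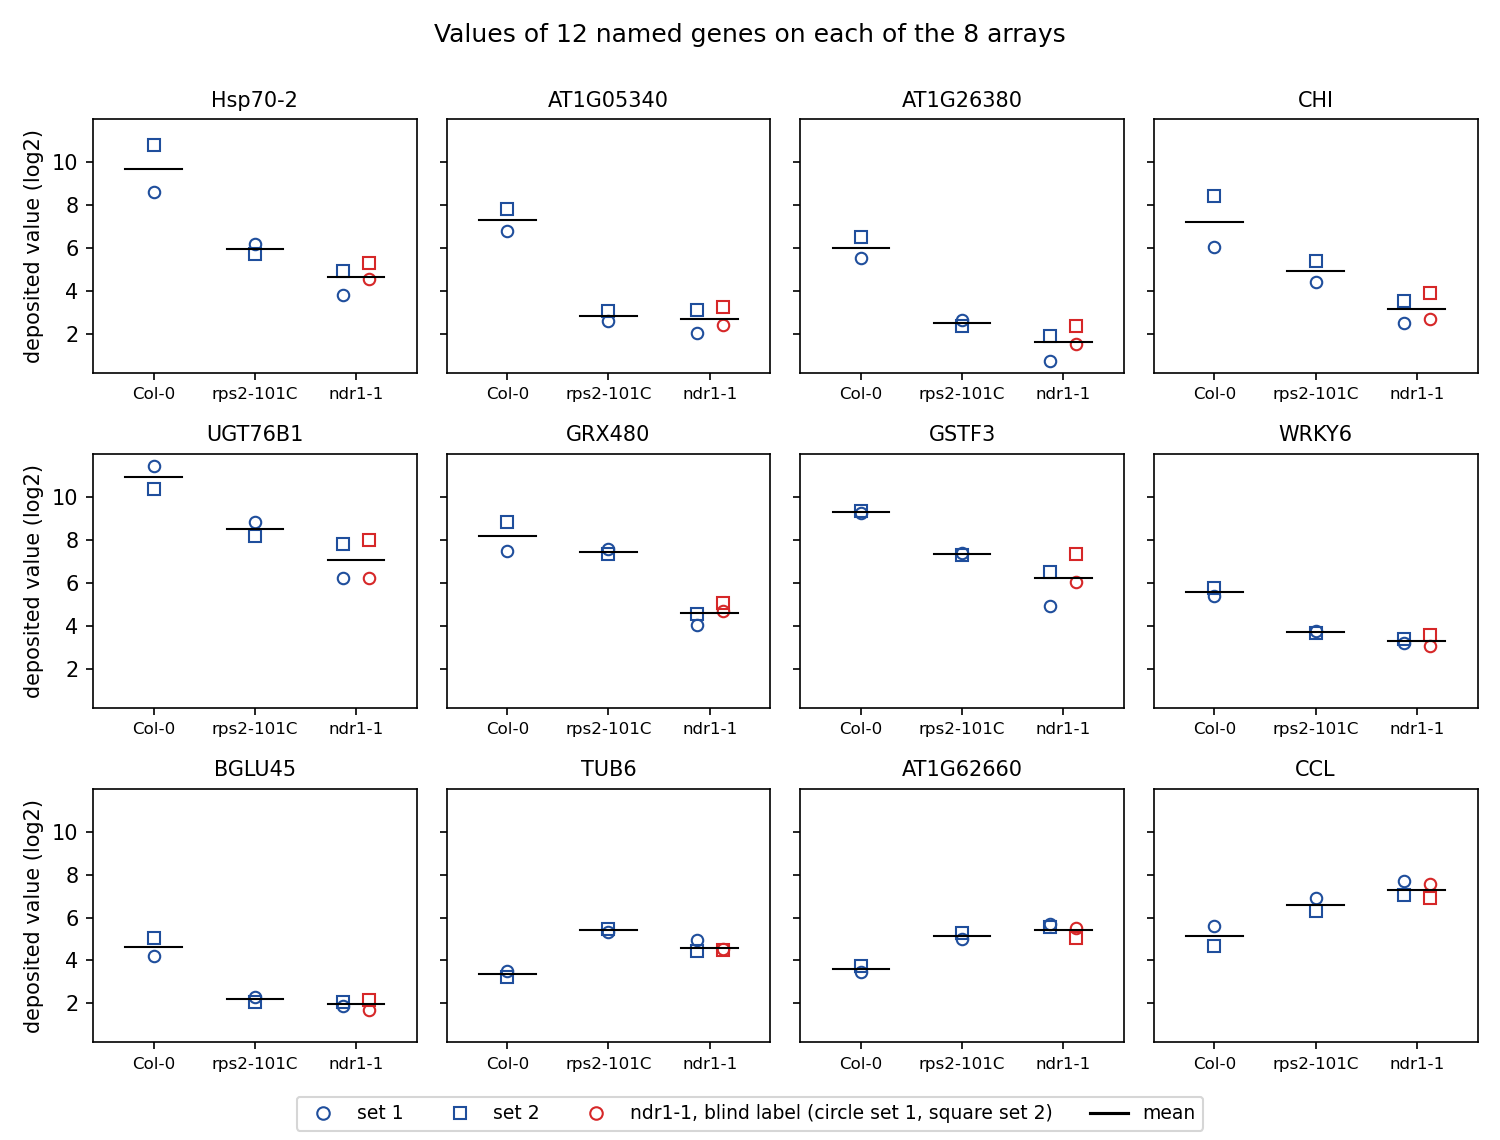
Deposited value (log2) of 12 named genes on each of the 8 arrays, by genotype, with circles for set 1, squares for set 2, red for the blind label and a line at the mean. AT1G05340 had a mean of 7.32 in Col-0, 2.83 in rps2-101C and 2.70 in ndr1-1; TUB6 had a mean of 3.38 in Col-0, 5.40 in rps2-101C and 4.60 in ndr1-1.

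The chaperones were the list with the largest mean change in ndr1-1: 5 of 5 were lower, also 5 when adjusted over the list alone, with a mean of -2.77. Besides Hsp70-2 and AT3G09440, these were AT2G29500 at -2.21 (adjusted p = 0.00511), the endoplasmic reticulum HSP70 BIP1 (AT5G28540) at -1.63 (adjusted p = 0.032) and the FKBP-type protein AT5G48570 at -1.02 (adjusted p = 0.048). The list passed fry (adjusted p = 0.0472; 0.0521 with the set as a block) and did not pass camera, which compares it with the other probes (adjusted p = 0.173; adjusted p = 0.859 with an estimated correlation). Here and below, the list tests treat the ndr1-1 arrays of both labels as independent and were not run with the labels averaged. Their p-values in ndr1-1 may therefore be too small. With median centring its mean was -2.12 and 3 of 5 members passed. The calls of BIP1 and AT5G48570 ended with both scalings, without either Col-0 array and without either set 1 ndr1-1 array, that of BIP1 also without either rps2-101C array and that of AT5G48570 without either set 2 ndr1-1 array.

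Of the 4 WRKY transcription factors, 1 was lower in ndr1-1, WRKY6 at -2.28 (SE 0.29, adjusted p = 0.000793), and 1 when adjusted over the list alone. WRKY22, WRKY29 and WRKY53 had values of -1.19, -1.22 and -1.19 with adjusted p-values of 0.0917, 0.125 and 0.27, of which the first 2 became 0.0301 and 0.04 with the set as a block. The WRKY mean was -1.47, and -0.82 with each array centred (camera adjusted p = 0.511, adjusted p = 0.859 with an estimated correlation, fry adjusted p = 0.0628). Several lists fixed before the data were examined had a single member among the named probes. For salicylic acid this was GRX480, a salicylic acid-inducible glutaredoxin, with the value above. For oxidative stress it was the glutathione transferase GSTF3 (AT2G02930), lower at -3.10 (SE 0.51, adjusted p = 0.00242). For tryptophan and camalexin it was the indole-3-glycerol phosphate synthase AT2G04400, lower at -1.75 (SE 0.32, adjusted p = 0.00384). In rps2-101C these last 2 genes had values of -1.96 (adjusted p = 0.0649, and 0.0208 with the set as a block) and -0.87 (adjusted p = 0.168). The defensin PDF1.2 (AT5G44420), from the jasmonic acid list, had a value of 0.39 (SE 0.45, adjusted p = 0.547), and 0.57 (adjusted p = 0.555) in rps2-101C. The translation elongation factor AT5G60390, from the housekeeping list, had -0.23 (SE 0.29, adjusted p = 0.575), and 0.05 (adjusted p = 0.951) in rps2-101C.

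The receptor-like kinases and the UDP-glycosyltransferases also passed fry in ndr1-1, each at an adjusted p of 0.0472, which became 0.0521 and 0.0695 with the set as a block. These passes, too, treat the ndr1-1 arrays of both labels as independent. With each array centred these lists did not pass fry (adjusted p = 0.255 and 0.931), had means of -0.20 and -0.18 and had 1 lower member each. Of 4 receptor-like kinases, 2 were lower, AT3G09010 at -2.21 (adjusted p = 0.0103) and AT2G23450 at -1.29 (adjusted p = 0.0103), with a list mean of -0.84. Of 7 UDP-glycosyltransferases, 2 were lower, UGT76B1 and UGT76E12 (AT3G46660), the latter at -0.93 (adjusted p = 0.0312), with a list mean of -0.83. Both lists also had 2 lower members when adjusted over the list alone and did not pass camera (adjusted p = 0.781 each). Of 5 EF-hand calcium-binding proteins, 2 were lower, AT5G39670 at -1.26 (adjusted p = 0.0445) and AT2G41410 at -1.14 (adjusted p = 0.0231), and 3 when adjusted over the list alone, with a mean of -1.16 (fry adjusted p = 0.0582), which was -0.51 with median centring and -0.28 with quantile normalization. Of 7 membrane traffic genes, 2 were lower, PRA1.B4 (AT2G38360) at -1.35 (adjusted p = 0.00782) and AT2G34250 at -1.03 (adjusted p = 0.0312), and 3 when adjusted over the list alone. The membrane traffic mean was -0.36 and its median 0.04, and the mean was 0.28 with median centring and 0.16 with quantile normalization (fry adjusted p = 0.0559). CHI was the 1 of 4 chitinase and PR-6 genes that passed (mean -1.16, and -0.51 with each array centred), AT1G03220 the 1 of 4 aspartyl protease family members (mean -0.86, and -0.21 centred), and AT4G40030 the 1 of 3 histone H3 genes (mean 0.39, higher, and 1.04 centred). With centring AT5G19110 of the aspartyl protease family (adjusted p = 0.0296) and the histone H3 gene AT5G65360 (adjusted p = 0.0481), both named after their values were seen, were higher. On the deposited scale AT5G19110 lay at 2.92 on the set 2 blind array and between 1.02 and 1.15 on the other ndr1-1 arrays. With the set as a block, CML42 of the EF-hand list (adjusted p = 0.0458), AT1G47830 of membrane traffic (adjusted p = 0.0464) and AT3G51330 of the aspartyl protease family (adjusted p = 0.0437), named after their values were seen, were also lower. AT1G03220 lay at -2.84 (SE 0.37, adjusted p = 0.000793). The calls of UGT76E12, AT5G39670, AT2G41410, AT2G23450 and AT2G34250 ended with both scalings and without the set 1 Col-0 array, that of PRA1.B4 ended with median centring, and that of AT3G09010 without the set 2 Col-0 array. Those of UGT76E12, AT5G39670, AT2G41410 and AT2G34250 also ended without the set 2 Col-0 array or the set 1 ndr1-1 array. Without the set 1 blind array those of UGT76E12, AT5G39670 and AT2G34250 ended, without the set 2 ndr1-1 array those of UGT76E12 and AT2G41410, without the set 2 blind array that of AT2G41410, and without either rps2-101C array that of AT5G39670.

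On the deposited scale, without the block, no member passed in 4 lists in ndr1-1, and with each array centred some did. The class III peroxidases had a mean of 0.30, and 0.95 with centring, with AT2G37130 at 0.99 (adjusted p = 0.0945, and 0.0124 with centring) and AT5G19890 at 0.14 (adjusted p = 0.797). The sulfur assimilation and glucosinolate genes had a mean of 0.15, and 0.80 with centring, with AT2G25450 at 1.34 (adjusted p = 0.058, 0.0133 with centring and just under the threshold with the block) and UGT74B1 (AT1G24100) at -0.69 (adjusted p = 0.282). The vacuolar proton ATPase subunits had a mean of 0.11, and 0.76 with centring, with AT4G32530 at 0.43 (adjusted p = 0.353, and 0.0332 with centring) and AT2G16510 at -0.31 (adjusted p = 0.616), which lay at 0.34 with median centring. The respiratory chain subunits had a mean of -0.09, which was 0.56 with median centring, with SDH1-1 (AT5G66760) at -0.70 (adjusted p = 0.131) and AT4G02580 at -0.11 (adjusted p = 0.849), which lay at 0.54 with median centring. AT4G37830 of this list, named after its values were seen, lay at 0.42 (adjusted p = 0.298, and 0.0222 with centring). With each array centred, the chaperones passed fry in ndr1-1 as lower (adjusted p = 0.027). The vacuolar proton ATPase and histone H3 (adjusted p = 0.0191 each) and the respiratory chain (adjusted p = 0.027) passed it as higher. Fry compares a list with 0 and centring adds 0.65 to every change, so the higher passes may come from that constant alone. On the deposited scale the fry adjusted p-values of these lists were 0.0903, 0.244 and 0.69, in that order. Camera called none of the 13 lists in either mutant, which says little, as it called 0% to 13.5% of simulated lists shifted by -1.5 (log2) among probes with the observed changes.

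**Figure D3:**
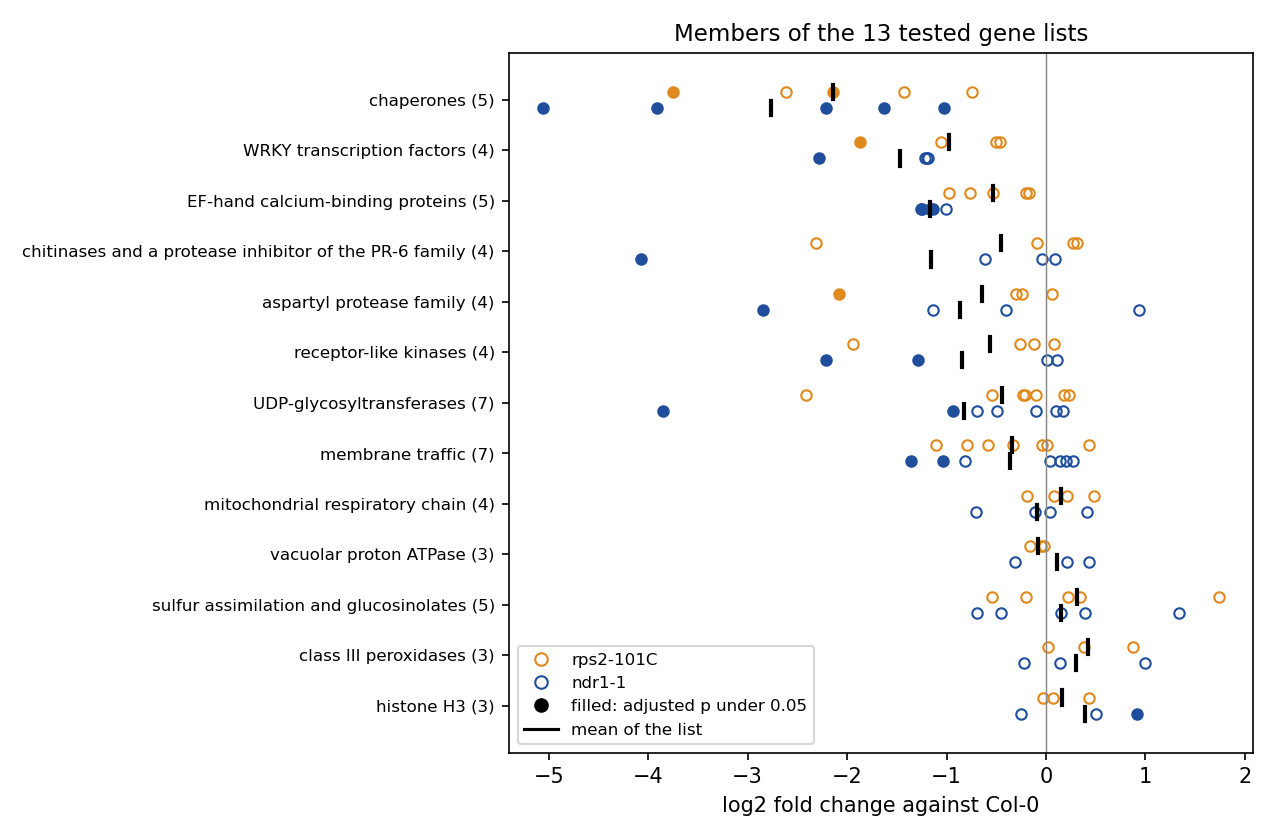
Log2 fold change against Col-0 of each member of the 13 tested gene lists in rps2-101C (orange) and ndr1-1 over both labels (blue), with the number of members in brackets. Filled circles passed an adjusted p under 0.05, and bars mark list means; all 5 chaperones lie below 0 in both mutants, with means of -2.14 and -2.77.

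The overlap of the 2 mutants was compared across all probes. All 57 probes lower in rps2-101C were among the 160 lower in ndr1-1, against 15.8 expected for independent calls, and all 16 higher were among the 48 higher, against 1.33. A further 103 probes were called lower and 32 higher in ndr1-1 and not in rps2-101C, which does not by itself show a difference between the mutants. Both comparisons use the same Col-0 arrays. In 100 simulations of unchanged mutants sharing the controls, the mean number of shared calls was 0.01. With no gene changed few probes can be called at all, so this does not show how far the shared controls raise the overlap. Across probes, which are not independent replicates, the 2 sets of log2 fold changes correlated with a Pearson r of 0.921 and a Spearman rho of 0.891, against a simulated r of 0.578. Their covariance was 1.48, against 0.118 simulated. The change had the same sign in 84.2% of probes, against 69.7% simulated. Within sets, which share a single Col-0 array, r was 0.816 in set 1 and 0.901 in set 2, against a simulated mean of 0.578 (0.473 to 0.662 over 100 simulations). The 2 Col-0 arrays could not be divided into separate controls with 2 arrays each. The simulated values give only the agreement that shared controls bring when no gene changes, and do not replace such a division.

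The labels ndr1-1 and ndr1-1blind give a comparison of 1 genotype with itself, which the study used to set a false discovery rate. None of the 576 probes was called by limma between them (1 at an unadjusted p under 0.05; 0 called and 11 at an unadjusted p under 0.05 with the set as a block). Both unadjusted counts lie below a share of 0.05 of the probes. Set variation that the labels share cancels in their difference, while the error of the fit without the block includes it. The test is therefore conservative, and 0 calls are weak evidence that the labels match. The named genes with the smallest p were AT2G05910 at -0.72 (SE 0.36), AT2G41410 at 0.66 (SE 0.36) and GSTF3 at 1.01 (SE 0.59), each with an adjusted p of 1. The SD of the differences over all probes was 0.34, against 1.46 for ndr1-1 over both labels minus Col-0. The first of these leaves out set variation that the labels share. Arrays of the 2 labels correlated across probes with r of 0.980 in set 1 and 0.979 in set 2, pairs from within a set. Between sets, r was 0.945 for ndr1-1, 0.922 for ndr1-1blind, 0.933 for Col-0 and 0.954 for rps2-101C. Against Col-0, ndr1-1 alone had 174 calls (35 higher, 139 lower) and ndr1-1blind alone 151 (24 higher, 127 lower), which became 207 and 180 with the set as a block. With median centring the splits were 99 higher and 90 lower, and 69 higher and 73 lower. After quantile normalization they were 82 higher and 83 lower, and 66 higher and 73 lower. Both labels called 119 of the same probes lower, against 30.6 expected for independent calls, and 24 of the same probes higher, against 1.46. Their log2 fold changes, which share the Col-0 arrays, correlated across probes with r of 0.979, against 0.495 simulated. The simulation drew the 2 labels as independent arrays, while their set deviations correlated at 0.77. The simulated r and the numbers expected for independent calls leave out this shared variation. Both are therefore too low to show how well the labels match. Without the set 2 Col-0 array the counts were 96 and 72. The count for ndr1-1 was 88 without its set 1 array, and that for ndr1-1blind was 76 without its own set 1 array and 98 when fitted with Col-0 alone.

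The direct comparison of ndr1-1 with rps2-101C asks whether the 2 mutants differ. GRX480 had the largest named difference: its mean was 8.17 ± 0.96 (SD, n = 2) in Col-0, 7.45 ± 0.18 (SD, n = 2) in rps2-101C and 4.58 ± 0.43 (SD, n = 4) in ndr1-1. The log2 fold change of ndr1-1 minus rps2-101C was -2.87 (SE 0.42), with an adjusted p of 0.0568, and 0.0203 with the set as a block. GRX480 in rps2-101C did not pass against Col-0, at -0.73 (SE 0.48, adjusted p = 0.388). None of the 576 probes was called by limma, with 77 at an unadjusted p under 0.05. With the set as a block, 19 probes were called, 1 higher and 18 lower in ndr1-1, and a statistic modelled on SAM called 91. The null of that statistic, the blind label minus ndr1-1, leaves out variation between the sets, which the labels share, so its threshold can be too low. The block assumes a set effect shared by all labels. Set deviations correlated at 0.77 between ndr1-1 and ndr1-1blind and at 0.44 and 0.37 between Col-0 and these, while those of rps2-101C correlated at only -0.06 and 0.08 with the ndr1-1 labels. With the set numbers of rps2-101C crossed, 18 probes were called, all lower, of which 13 were among the 19. The blocked adjusted p-values of this comparison therefore rest on a pairing that is not stated and not seen between rps2-101C and ndr1-1. The named genes among the 19 were GRX480, CHI, AT3G28540 and AT5G52760. AT3G28540, an AAA-type ATPase, differed by -2.14 (SE 0.56, adjusted p = 0.157, and 0.03 with the block), AT5G52760, a heavy-metal-associated-domain protein, by -1.56 (SE 0.45, adjusted p = 0.201, and 0.0478 with the block) and CHI by -1.76 (SE 0.70, adjusted p = 0.323, and 0.0421 with the block). These 4 names were chosen after their values were seen. With crossed set numbers the adjusted p was 0.0103 for GRX480, 0.137 for CHI, 0.072 for AT3G28540 and 0.0872 for AT5G52760. For these 4 genes, the other alternatives examined were the set block, median centring, quantile normalization and leaving out each array. Over these the log2 fold change of GRX480 ran from -3.00 to -2.55 and that of CHI from -2.24 to -1.27. That of AT3G28540 ran from -2.63 to -1.66 and that of AT5G52760 from -1.87 to -1.26. The adjusted p of each was highest without the set 2 rps2-101C array, where none passed. With each array centred, the limma adjusted p of GRX480 was 0.0596. The count was 8 without the set 2 ndr1-1blind array and 1 without either Col-0 array. No list was called: the smallest adjusted p was 0.581 by camera and 0.155 by fry (vacuolar proton ATPase), and the WRKY and chaperone means differed by -0.50 and -0.63. The WRKY difference ran from -0.87 without the set 2 blind array to -0.12 without the set 1 blind array.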

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

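A check on whether 1 of the 4 ndr1-1 arrays stood apart picked out 2 of 55 named genes. Chance gives about 1 in 20 for independent arrays, which these are not, so that rate is only a rough guide. The value is the gap from the extreme array to its nearest neighbour as a share of the whole range. AT2G25450 had a share of 0.838, with the set 1 ndr1-1 array at 8.83 and the other 3 between 8.24 and 8.33. AT4G32530 had a share of 0.933, with the set 1 ndr1-1 array at 5.38 and the other 3 between 6.10 and 6.15. Neither gene was called in ndr1-1 without the block and without centring, and both were called with each array centred (adjusted p = 0.0133 and 0.0332). No explanation was tested for either. The check did not cover every gene named above. AT5G19110 was not among the 55, although it lay at 2.92 on the set 2 blind array and between 1.02 and 1.15 on the other ndr1-1 arrays.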

How the results depend on the processing

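Centring on reference genes, crossing the set numbers of rps2-101C and averaging the ndr1-1 labels within sets were chosen after seeing the data. Of the 67 named-gene results, 53 kept their side of the threshold with median centring, 51 with quantile normalization and 63 with the set block, and the other 14 and 16 were weaker and the other 4 stronger. Those 4 were GRX480, CHI, AT3G28540 and AT5G52760 in ndr1-1 minus rps2-101C. They entered that comparison because the block called them, so their change with the block was fixed in advance. Over all single-array omissions, 400 were the same, 132 weaker and 4 stronger. None reversed. The set block changed the counts to 117 for rps2-101C, 243 for ndr1-1 over both labels, 207 for ndr1-1, 180 for ndr1-1blind and 19 for ndr1-1 minus rps2-101C, and crossed set numbers gave 133 for rps2-101C and 18 for ndr1-1 minus rps2-101C. Averaging the labels gave 82 for rps2-101C, 163 for ndr1-1 and 0 for ndr1-1 minus rps2-101C. Fitting only the compared groups gave 98 for ndr1-1blind and 1 for ndr1-1 minus rps2-101C, which was 2 with centring on reference genes. The statistic modelled on SAM gave 165 for rps2-101C, 340 for ndr1-1 over both labels, 311 for ndr1-1, 276 for ndr1-1blind and 91 for ndr1-1 minus rps2-101C; its null leaves out variation between sets, so these can be too many. It tolerates 7, 17, 15, 13 and 4 calls between the blind label and ndr1-1, and gives no value for that comparison. Leaving out 1 array gave 0 to 83 for rps2-101C, 115 to 219 for ndr1-1 over both labels, 88 to 181 for ndr1-1, 72 to 147 for ndr1-1blind and 0 to 8 for ndr1-1 minus rps2-101C. The comparison of the blind label with ndr1-1 stayed at 0 in each setting run. The correlation of the mutants' fold changes ran from 0.871 to 0.944 over the omissions. An array left alone in its group is assumed to vary like the others, and omissions also leave fewer degrees of freedom; otherwise the cause was not tested. Centring on the housekeeping list was not run, as 1 of its genes was among the named probes, and an offset before the log was not run, as the values are logs. Background is not given, so how far dim probes lie above it is unknown.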

Other observations

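The genes in this paragraph lie outside the naming rule and were chosen after their values were seen. Of the 15 named genes lower in rps2-101C, 4 were described nowhere above. The autophagy gene ATG8E was lower by -1.48 (adjusted p = 0.0287) in rps2-101C and -2.09 (adjusted p = 0.00136) in ndr1-1. AT3G28510, an AAA-type ATPase, was lower by -1.97 (adjusted p = 0.0203) and -2.78 (adjusted p = 0.000793). AT2G36950, a heavy-metal-associated-domain protein, was lower by -1.36 (adjusted p = 0.0459) and -1.60 (adjusted p = 0.00553), and AT1G27100 by -1.71 (adjusted p = 0.0472) and -1.66 (adjusted p = 0.0127). All 4 rps2-101C calls ended without either rps2-101C array or without the set 2 Col-0 array, and with quantile normalization. Those of ATG8E, AT2G36950 and AT1G27100 also ended with median centring and without the set 1 Col-0 array, and those of the last 2 without either array labelled ndr1-1. In ndr1-1, the heavy-metal-associated-domain genes AT5G52760 and AT5G60800 were lower by -3.05 (adjusted p = 0.00149) and -2.70 (adjusted p = 0.00242), the AAA-type ATPase AT3G28540 by -2.48 (adjusted p = 0.0105) and AT2G18690 by -2.98 (adjusted p = 0.00243). The call of AT3G28540 ended without either Col-0 array, that of AT1G27100 without the set 2 Col-0 array and with median centring, and that of AT2G36950 with both scalings.

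The tests of array-wide scaling, of handling shared within a set and of the deposited scaling were chosen after the result was seen. The 57 probes lower in rps2-101C than in Col-0 lay lower still in ndr1-1, with a median difference between the mutants of -0.51. The median was -0.78 in set 1 (51 of 57 lower) and -0.36 in set 2 (39 of 57 lower). A single mutant array is argued against, as the highest median with 1 mutant array left out was -0.36 on the deposited scale. The omissions were not run with each array centred. Leaving out 1 ndr1-1 array of set 1 keeps the other label of that set (r of 0.980 between them), so a larger part from the set 1 leaves is not excluded. With each array centred, the median was -0.25 (95% bootstrap interval over genes -0.50 to -0.02), so a part due to array-wide scaling cannot be told apart from a larger effect of ndr1-1, because the interval covers genes and not arrays and reaches values near 0. The 16 probes higher in rps2-101C had a median of 0.17 above it in ndr1-1 (12 of 16 higher, 95% bootstrap interval -0.28 to 0.35) and of 0.43 (interval 0.02 to 0.61) with each array centred, which adds 0.26 to every difference; the centred intervals of both groups leave out 0 by 0.02, and the deposited one does not leave out a downward shift of 0.26.

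The ndr1-1 arrays differed between the sets by a median absolute difference, array for array, of 0.43 in each label, against 0.43 in rps2-101C and 0.55 in Col-0. The set differences of rps2-101C and ndr1-1 correlated across probes with r of 0.012 (95% bootstrap interval -0.0766 to 0.101). This argues against a handling difference shared by every genotype of a set. It does so only if the set numbers mark the same handling in each genotype, which is not stated. The bootstrap intervals here cover probes and not arrays, and rps2-101C had 2 arrays. The set differences of Col-0 and ndr1-1 correlated with r of 0.431, so handling shared by these genotypes and not by rps2-101C stays open. The ndr1-1 set difference correlated with the rps2-101C minus Col-0 change with r of -0.342 (95% bootstrap interval -0.415 to -0.269), which is consistent with the genes changed in rps2-101C differing in level between the sets of ndr1-1 leaves. That of Col-0 correlated with the same change with r of -0.493, a value that shares the Col-0 arrays, and a difference between arrays in how signal grows with RNA was not tested.

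More probes were lower than higher in ndr1-1 on the deposited scale, 160 against 48. If the deposited scaling were the source, 15 reference genes (respiratory chain, vacuolar proton ATPase, membrane traffic and AT5G60390) would shift by at least 0.5 times the median shift, which is -0.18. Their mean shift was -0.19 (SE 0.14, interval -0.47 to 0.10), which lies at that bound and includes PRA1.B4 and AT2G34250, called lower in ndr1-1. Their median was 0.04 (95% bootstrap interval -0.31 to 0.21), an interval that also holds the bound, and how the authors normalized the arrays is not known. A shift from scaling and a wider decrease in ndr1-1 cannot be told apart for these reasons.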
